A study of Rattus norvegicus with 2 samples.

How the data were processed

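Gene expression was measured with Affymetrix arrays in AT6.1 cells, an established rat prostate cancer cell line. One clone had been transfected with the pcDNA3 expression vector carrying N-myc downstream regulated gene-1 (Ndrg-1, gene symbol Ndrg1), and 1 clone had been transfected with the vector without an insert. Per the labels' protocols, cells grew in RPMI medium with 10% fetal calf serum and were kept under selection with 0.3 mg/mL G418, RNA was extracted with TRIzol, and biotin-labelled target was made by the manufacturer's protocol. There was 1 array per group and no replicate, so no p-value could be given for any comparison. Clone, culture and array each coincide with the group, and their share in a difference cannot be told apart from that of the insert.

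The deposited values are 1 intensity (probe set signal, linear scale) per probe set and array. They were made with GCOS 1.3, per the submitters' processing notes. The probe set summary, detection calls and scaling setting are not given in the sources used here. All 31099 probe sets had a value above 0. The mean signal without the lowest and highest 2% of probe sets was 150.0 in both arrays, so the deposited intensities had been scaled to a common level before deposit. The deposited table gave no detection calls or p-values, and the precision of each value is limited by the number of arrays.

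The 57 control probe sets were set apart. Among the other 31042 probe sets, 20826 carried 1 gene symbol in the platform annotation, 436 carried several and 9780 carried none. Of the probe sets with 1 symbol, 20758 matched a gene of the RefSeq annotation of the rat assembly GRCr8 by gene ID. That annotation was used for names and for which genes neighbour each other. No genome build is named for the array table, so no coordinates are given.

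The following settings were fixed before the data were examined. The vector array was rescaled so that the median log2 ratio of probe sets with a mean log2 signal above the overall median was 0, a shift of 0.0050. The floor was the median of all signals in both arrays, 31.0, which lies near the lowest of the bioB hybridisation spikes at 28.8. Signals under the floor were set to it before log2 was taken, and a gene at the floor in 1 array has only a lower bound ("at least N-fold"). Each gene was represented by its probe set with the highest mean log2 signal, which gave 14217 genes, of which 9181 were above the floor in at least 1 array and 8552 in both. A difference was counted when it reached 2-fold. With no replicate arrays, the only error in the table is the disagreement between probe sets of a gene. Its SD was computed on the log2 ratio over 5336 probe sets of 2296 genes that were above the floor in both arrays. It leaves out variation between cultures, clones and arrays.

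Named genes followed a fixed rule. It takes all probe sets of Ndrg1, the 10 highest and the 10 lowest log2 ratios among genes above the floor in both arrays, and the 5 brightest genes per direction among those at the floor in the other array. It adds up to 4 members per direction and list that reached 2-fold, or up to 2 members of a list in which none did. Gene lists for 37 pathways, complexes and cell types were also fixed beforehand. For each, the median log2 ratio of members above the floor in at least 1 array was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. The percentile describes these 2 arrays and is not a p-value.

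The procedure was tested on simulated data made from the real signals, with 200 genes changed, for the comparison of the Ndrg-1 array with the vector array. Of genes changed 3-fold, 97% were counted in the right direction, and of genes changed 6-fold, 100%. Of 8813 unchanged measured genes, 1 reached 2-fold. Of random lists of unchanged genes, 7% fell outside the central 95%. The changed genes were drawn from those with a mean signal above that of the median gene. The simulated noise was independent between probe sets and of the size of the disagreement between probe sets of a gene. It left out variation between clones, cultures and arrays, so these shares are not error rates for the real comparison. Alternatives were no rescaling, quantile normalization, removal of a lowess trend of the log2 ratio on signal, floors at the 25th and 75th percentiles, a pseudocount of 16 with no floor, the median over a gene's probe sets, and leaving out probe sets with _x_at or _s_at identifiers. Scaling to the spiked controls was added after seeing the data, as were some named genes that the rule does not cover, each said to be so where it appears. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.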

Results

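Expression was compared between 2 arrays of AT6.1 rat prostate cancer cells, 1 from a clone transfected with Ndrg-1 and 1 from a clone transfected with the empty vector (1 array per group, no replicates). The series sought genes that differ between cells with high Ndrg-1 and the vector control. The arrays had median signals of 31.1 and 31.2. Log2 signals correlated across probe sets with Pearson r = 0.943, and with r = 0.972 across probe sets above the floor in both arrays. Probe sets are not independent replicates. RNA quality was similar by the control probe sets, with a 3' to 5' signal ratio for Actb of 1.21 in the Ndrg-1 array and 1.24 in the vector array, and for Gapdh of 1.05 and 1.03.

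The transfected gene was not 2-fold higher in the Ndrg-1 array. Ndrg1, a stress- and differentiation-regulated gene that is described as a metastasis suppressor, was represented by 2 probe sets. The brighter had a signal of 1353 in the Ndrg-1 array and 1066 in the vector array, a log2 ratio of 0.34. The dimmer had signals of 154 and 182, a log2 ratio of -0.24. Both lay within 2 SD of the disagreement between probe sets of a gene (SD 0.23 on the log2 scale). Among genes with a mean signal of at least 271 the SD was 0.18 and 2 SD were 0.36, just above the ratio of the brighter probe set. The brightest decile of probe sets, in which that probe set lies, had a median log2 ratio of -0.13. In the vector array the signal of the brighter probe set exceeded that of 95.6% of all probe sets, and the dimmer that of 76.0%. Such ranks compare different probe sets and do not measure how abundant the transcript was. The extent and species of the insert are not given in the sources used here, so probe sets in the untranslated 3' end of the rat transcript may not read the transfected copy. The related genes Ndrg2, Ndrg3 and Ndrg4 had log2 ratios of -0.44, -0.08 and -0.36.

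Between the arrays, 149 genes were at least 2-fold higher and 138 at least 2-fold lower in the Ndrg-1 array, together 3.13% of the 9181 genes measured. The vector array lay at the floor for 53 of the higher genes and the Ndrg-1 array for 35 of the lower genes. At 4-fold, 26 genes were higher and 19 lower. A further probe set above the floor was available for 36 of the higher genes and went the same way in 34, reaching 2-fold in 16. It was available for 35 of the lower genes and went the same way in 35, reaching 2-fold in 16. The split between higher and lower depends on the scaling. The 18 hybridisation spike probe sets were all lower in the Ndrg-1 array (median log2 ratio -0.54), while 23 of the 24 poly-A spike probe sets were higher (median 0.21). Scaled to the hybridisation spikes, 732 genes were higher and 43 lower, and scaled to the poly-A spikes 101 were higher and 240 lower. All ratios are therefore given relative to the median gene, which those scalings moved by 0.54 and -0.21.

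**Figure D1:**
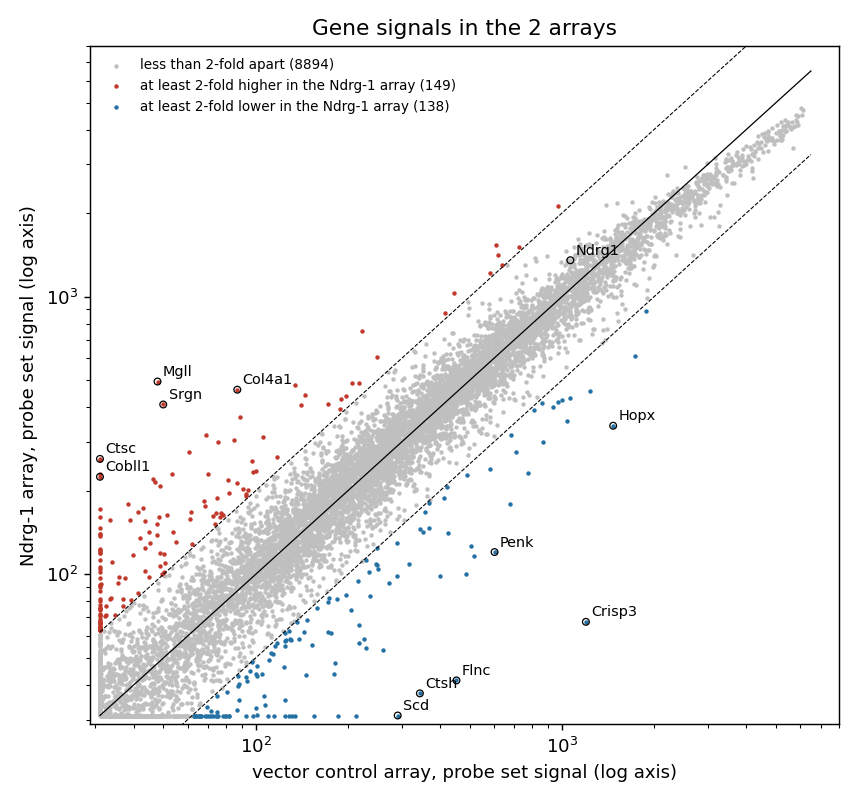
Each point is 1 gene, with its probe set signal in the vector control array on the horizontal axis and in the Ndrg-1 array on the vertical axis (both log axes; signals below the floor of 31.0 are drawn at it). Solid and dashed lines mark equal signals and 2-fold differences; 149 genes lie above the upper and 138 below the lower dashed line, and Ndrg1 lies between them.

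The highest ratio among genes measured in both arrays was that of Mgll, the monoglyceride lipase that releases fatty acids from monoacylglycerols, at 495 against 47.8 (10.3-fold). Its other 2 probe sets above the floor in the Ndrg-1 array were at the floor in the vector array, with log2 ratios of at least 2.91 and 2.49. Srgn, the core protein of the proteoglycan serglycin, was 8.19-fold higher, and Col4a1, a chain of basement membrane collagen, was 5.31-fold higher. The next were Ogfrl1 (4.74-fold), Tom1l1, an adaptor protein (4.71-fold), Gpr15lg (4.70-fold), the membrane skeleton adaptor Ank2 (4.61-fold), Irak1bp1 (4.59-fold), the cytoskeletal adaptor Sorbs2 (4.57-fold) and the kinase gene Rps6ka6 (4.31-fold). Irak1bp1, and Ctsh among the lower genes below, lie on a chromosome stretch that held 2 runs of neighbouring genes with higher signals in the Ndrg-1 array. Both lie between the runs. Irak1bp1 is among 92 genes with a median log2 ratio of -0.04, and Ctsh among the 21 directly before the second run, of which 18 were above 0 (median 0.47). Genes at the floor in the vector array were led by Ctsc, the lysosomal protease cathepsin C, which was at least 8.40-fold higher, with a further probe set also at the floor in the vector array. Casd1, a sialic acid acetyltransferase, was at least 8.31-fold higher, Mylk, the myosin light chain kinase, at least 7.41-fold, Cobll1 at least 7.24-fold, and the thrombin receptor F2r at least 5.54-fold.

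Crisp3, a cysteine-rich secretory protein, had the lowest ratio among genes measured in both arrays. Its signal was 67.5 in the Ndrg-1 array against 1198 in the vector array (17.8-fold lower). Flnc, the actin cross-linker filamin C, was 10.9-fold lower, and its other probe set had a log2 ratio of -1.38. The lysosomal protease Ctsh was 9.22-fold lower, and Penk, the enkephalin precursor, was 5.01-fold lower. The non-muscle myosin heavy chain Myh10 was 4.88-fold lower, the dystrophin-complex member Sspn 4.82-fold, the small heat shock protein Hspb7 4.45-fold (second probe set at a log2 ratio of -0.88), the transcriptional cofactor Hopx 4.29-fold, S100a13 4.25-fold and the acyl-CoA synthetase Acsbg1 4.14-fold. For Sspn, 3 of the 4 other probe sets measured were lower, with log2 ratios of -2.09, -2.10 and, at the floor in the Ndrg-1 array, -1.26 or lower. The fourth, at the floor in the vector array, was at 0.12 or more. At the floor in the Ndrg-1 array, Scd, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, was at least 9.38-fold lower. The synuclein gene Sncg was at least 6.85-fold lower, Als2cl at least 5.98-fold and the RNA decapping enzyme Dxo at least 4.33-fold. Btg3 had a signal of 155 in the vector array and lay under the floor in the Ndrg-1 array.

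Cholesterol synthesis genes were lower together in the Ndrg-1 array. Of the 22 measured members, 21 had a ratio below 0 and 1 reached 2-fold, with a median log2 ratio of -0.54. All 10000 matched random lists had higher medians (central 95% from -0.12 to 0.16). Insig1, which regulates sterol sensing, was 2.07-fold lower at 391 against 810. Members below 2-fold in this list and those that follow were chosen after their values were seen. They included here the reductase Dhcr7 (log2 ratio -0.97), the cyclase Lss (-0.93), Fdps (-0.90) and the epoxidase Sqle (-0.82). The transcription factor genes Srebf1 and Srebf2 were at -0.64 and -0.55, and Scap alone was above 0, at 0.34. In the list for fatty acid synthesis, storage and oxidation, 30 of 38 members were below 0, with a median of -0.17 at percentile 0.50. Besides Scd, the phosphatidate phosphatase Lpin1 was at least 4.14-fold lower, with a second probe set at a log2 ratio of -0.80, and the sterol exporters Abcg1 and Abca1 were 3.84-fold and 2.08-fold lower. The second probe set of Abcg1, at the floor in the Ndrg-1 array and near it in the vector array, was at -0.01 or lower. The fatty acid transporter Cd36 was the 1 member at least 2-fold higher (2125 against 971, 2.19-fold).

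Heat shock and stress genes stood higher than matched lists. The 17 heat shock genes had a median log2 ratio of 0.26 (percentile 100 of random lists, central 95% from -0.21 to 0.07), with 10 members above 0 and 7 below. Hspa1a, the inducible HSP70, was 2.58-fold higher, the co-chaperone Chordc1 was at 0.70 and Dnajb1 at 0.54, while Hspa4l was at -0.58. In the list of ATF4, CHOP and ER stress genes, 31 of 46 members were above 0 (median 0.12, percentile 99.95, central 95% from -0.12 to 0.05). Vldlr was 3.36-fold higher with its 3 other probe sets between 0.91 and 1.60, the ER chaperone Dnajb9 was 2.23-fold higher and the stress-induced transcription factor Atf3 at least 2.41-fold higher. Ddit3, which encodes CHOP, was at 0.96, and the ER chaperone Hspa5 was at -0.0018, turning to as much as 0.26 under other scalings.

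**Figure D2:**
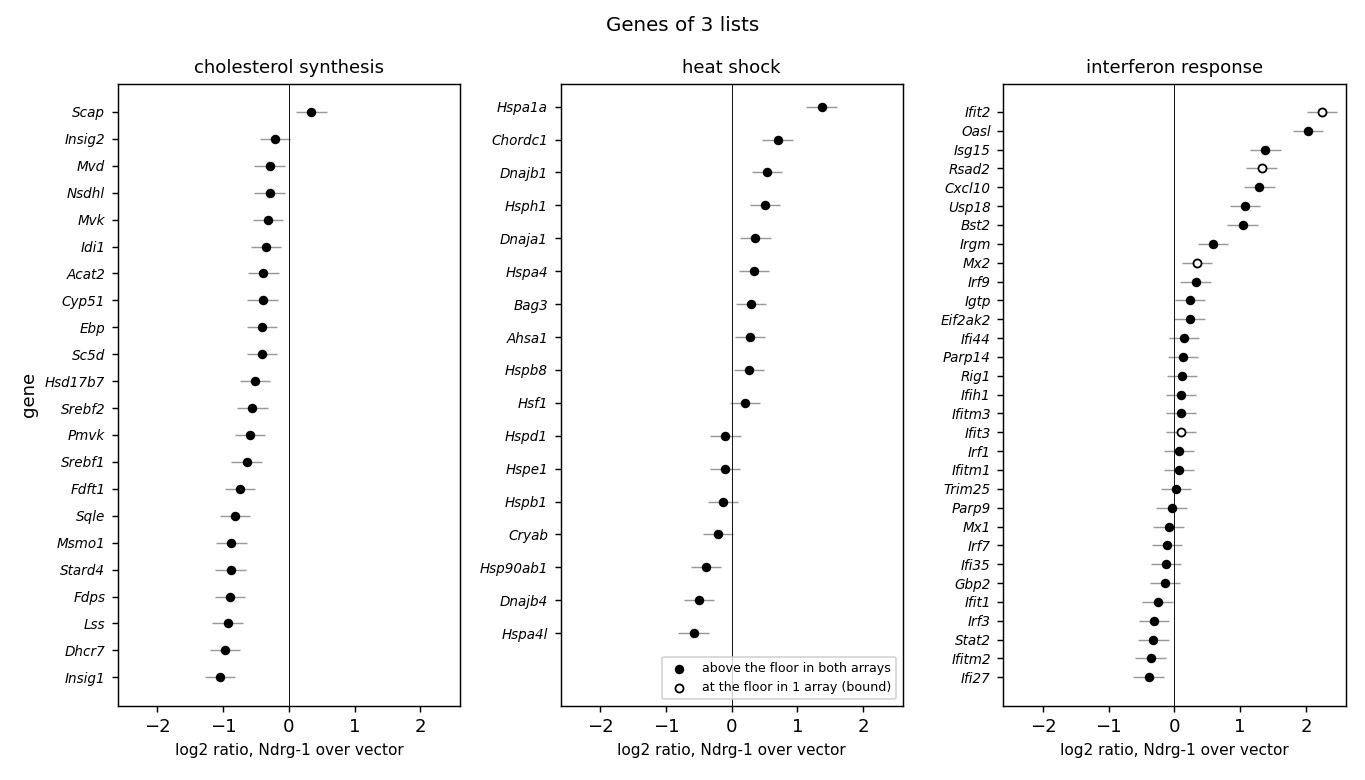
Log2 ratios (Ndrg-1 array over vector array, horizontal axis) of the measured genes of 3 lists, 1 gene per row; whiskers are 1 SD of the disagreement between probe sets of a gene (0.23), and open symbols are bounds for genes at the floor in 1 array. In the cholesterol list 21 of 22 genes lie below 0, and 7 interferon response genes lie at 1 or above.

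Interferon response genes held 7 members at least 2-fold higher and 0 lower among 31 measured, but the list median of 0.10 lay inside the range of random lists (percentile 88.3). The antiviral genes Oasl and Isg15 were 4.07-fold and 2.61-fold higher, the chemokine Cxcl10 2.45-fold and the ISG15 protease Usp18 2.10-fold. Other members such as Mx1 (-0.09), Irf7 (-0.11) and Stat2 (-0.32) did not reach 2-fold. Among cytokines, chemokines and NF-kappaB targets, 4 of 26 were at least 2-fold higher. These were the chemokines Ccl7 (2.91-fold) and Ccl2 (1535 against 612, 2.51-fold), the regulator Nfkbiz (2.91-fold) and Il6 (at least 2.13-fold), while Tnfaip2 was 2.05-fold lower, with a second probe set, at the floor in the Ndrg-1 array, at -0.08 or lower. In the immediate early list (median 0.11, percentile 97.1), Fos was at least 4.43-fold and Fosb at least 2.17-fold higher, as was Atf3, and the signalling inhibitor Spry4 was 2.47-fold lower.

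Matrix genes and proteases differed in both directions. In the mesenchymal and matrix list 20 of 31 members were below 0 (median -0.22, percentile 0.59). This list lay outside the random range in 5 of the 8 alternative settings, with a median of -0.03 at percentile 68.3 when the floor was at the 25th percentile. Col3a1 was 2.93-fold lower, whereas Col4a1, Col4a2 (3.32-fold) and Col1a1 (2.16-fold) were higher. In the protease list (median -0.20, percentile 0.94, outside the random range in 5 of the 8 alternative settings), Ctsh, Adam15 (2.47-fold) and Adam9 (2.03-fold) were lower, and Ctsc and Adamts4 (at least 2.09-fold) were higher. Among protease inhibitors, Timp4 and Serpinf1 were 2.39-fold and 2.04-fold lower and Slpi was 2.06-fold higher. Of the 33 epithelial and junction genes on the array, 9 were above the floor in at least 1 array. None of these reached 2-fold at this floor (median -0.19). The others, among them Cdh1, Epcam and Krt18, were under the floor in both arrays and could not be compared. The highest was Ctnnd1 at 0.40 and the lowest Cldn1, at the floor in the Ndrg-1 array, at -0.41 or lower (-1.42 with the floor at the 25th percentile).

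Of 22 metastasis suppressor genes and 16 Wnt and beta-catenin genes measured, 0 reached 2-fold at this floor. With the floor at the 25th percentile 2 of these Wnt genes did, Znrf3 and Ccn4. List members under the main floor in both arrays are left out of these counts. In these lists Cd9 was at 0.65, Cd82 at -0.53, Znrf3 at 0.98 or more with the vector array at the floor (1.83 with the lower floor), and Tcf7l2 at -0.73, and both list medians (-0.06 and -0.06) lay inside the range of random lists. Among genes tied to NDRG1 in earlier work, Atf3 was the 1 of 15 at least 2-fold different. Iron metabolism genes had a median of -0.04. Hmox1, the heme-degrading oxygenase, was 2.25-fold higher and the transferrin receptor Tfrc was at 0.78. In the remaining signalling lists, the receptor Nrp1 (4.14-fold, second probe set at 1.90), the co-receptor Eng (at least 2.94-fold), the vasodilator peptide Adm (3.05-fold), the lactate transporter Slc16a3 (3.17-fold), Gadd45a (2.44-fold) and Endog (at least 2.04-fold) were higher. Fgfr1 (3.79-fold), Bmp2 (3.56-fold), Bdnf (at least 2.64-fold), Tgfbi (at least 2.43-fold) and Igfbp7 (at least 2.34-fold) were lower. Gas6 was 3.21-fold higher on its brightest probe set, but its 2 other probe sets were at -0.57 and 0.16. The extracellular superoxide dismutase Sod3 was 4.04-fold lower and the actin-binding Lsp1 2.09-fold higher.

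Proliferation and housekeeping lists differed by small amounts. No measured member of the lists for G2 and mitosis (44 genes, median 0.06, percentile 98.0), S phase and DNA replication (46 genes, median -0.10, percentile 1.51), oxidative phosphorylation (57 genes, median -0.19, percentile 0.83) or ribosomal proteins (40 genes) reached 2-fold. Ribosomal protein genes had a median of -0.38 with 38 of 40 below 0, but quantile normalization placed the median at 0.01. The list lay outside the random range in 7 of the 8 alternative settings. Matched random lists already had medians of -0.11 for oxidative phosphorylation and -0.20 for ribosomal proteins. The ratio bent at high signal: in the brightest decile of probe sets above the floor in both arrays, the median log2 ratio was -0.13, and the highest signal was 4795 in the Ndrg-1 array and 6446 in the vector array. Of the 36 NRF2 and oxidative stress genes, 25 were below 0 (median -0.19, percentile 1.70).

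Markers of other cell types were mostly below the floor. Above it in at least 1 array were 5 of 26 macrophage and leukocyte markers on the array, 5 of 23 neural and neuroendocrine markers, 8 of 17 fibroblast and smooth muscle markers and 3 of 12 endothelial markers. Map2, a neuronal microtubule protein, had signals of 126 in the Ndrg-1 array and 505 in the vector array, and its second probe set had a log2 ratio of -1.06 or lower. The endothelial list (Eng, Egfl7 at 0.72, and Esam at 0.56 or more with the vector array at the floor) had a median of 0.72, which turned to -0.26 with the floor at the 25th percentile. Further list medians lay inside the random range. Those with a median above 0 were fibroblast and smooth muscle markers (0.05), cytokines, chemokines and NF-kappaB targets (0.06), TGF-beta signalling (0.0049) and genes tied to NDRG1 in earlier work (0.0025). Medians were -0.02 for angiogenesis, -0.03 for proteasome and for antigen presentation, -0.04 for p53 targets and for apoptosis regulators, and -0.05 for integrins and adhesion receptors. They were -0.07 for hypoxia and glycolysis, for housekeeping genes and for neural markers, -0.08 for the actin cytoskeleton and -0.11 for macrophage and leukocyte markers. They were -0.14 for growth factors and receptors, -0.21 for protease inhibitors, -0.22 for the NDRG family and -0.28 for prostate and androgen-regulated genes. In all, 12 of the 37 list medians lay outside the central 95% of random lists, 8 below and 4 above. In simulated data 7% of random lists of unchanged genes did so. That noise was independent between probe sets, and genes of a pathway that vary together between cultures were not simulated. The 7% is therefore not the share to expect for these lists, which also share members. Of the 287 genes at least 2-fold different, 55 belonged to a list and 232 to none.

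**Figure D3:**
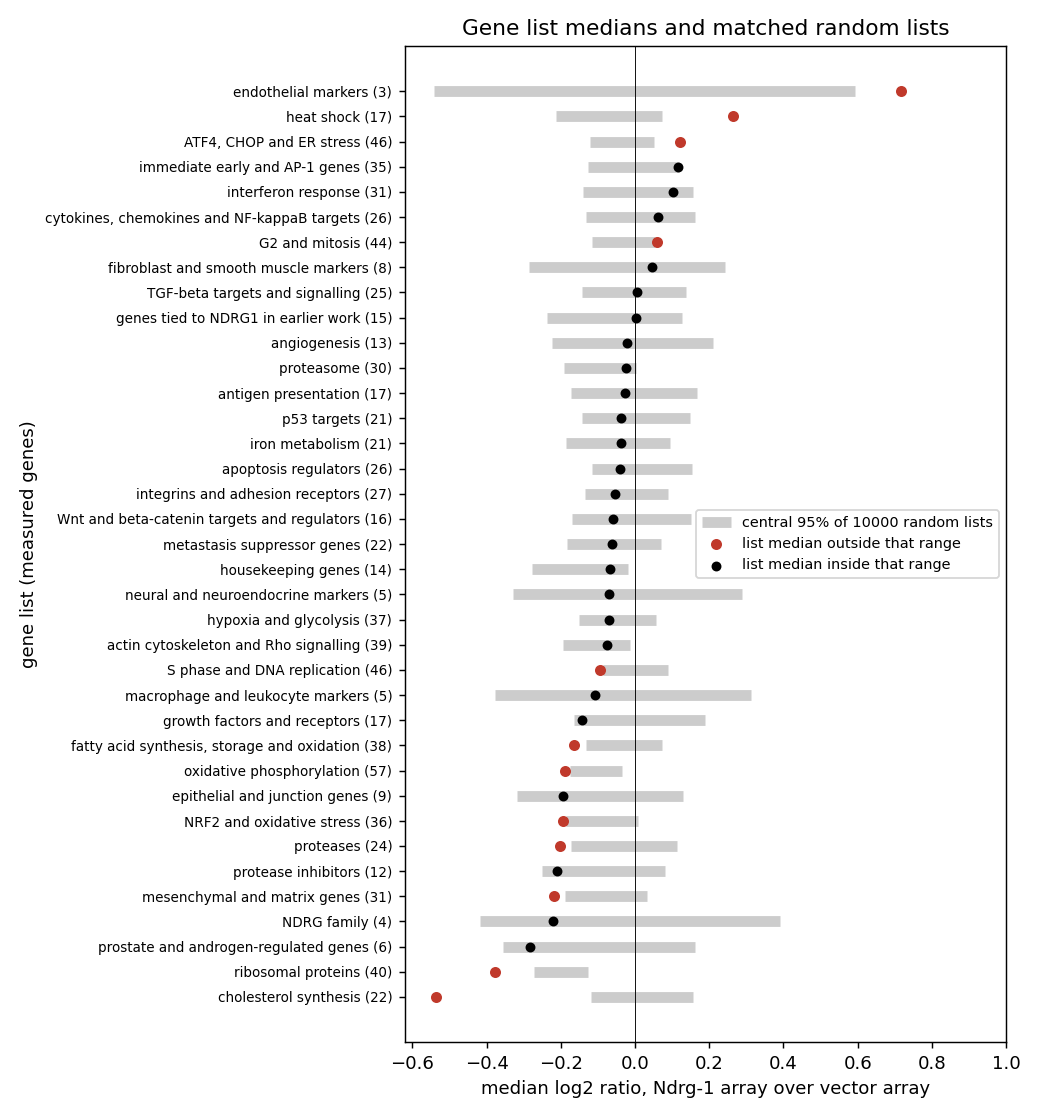
Points are the median log2 ratios (Ndrg-1 array over vector array, horizontal axis) of the 37 gene lists, with measured genes in parentheses, and grey bars are the central 95% of 10000 random lists matched on size and signal. Cholesterol synthesis lies farthest below its bar at -0.54, and heat shock lies above its bar at 0.26.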

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

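The tests on Ndrg1 below, of exchanged labels and of saturation, were chosen after its values were seen, and the second and the third test of saturation were each added after the result of the one before.

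In data outside the gene comparison, 53 probe sets without a single gene symbol were at least 2-fold higher in the Ndrg-1 array and 41 at least 2-fold lower, among 3709 above the floor. Among the highest ratios of these was a probe set at 826 in the Ndrg-1 array against 118 in the vector array (6.98-fold), and among the lowest was a probe set at least 8.67-fold lower. The 5S rRNA control probe set was 1.76-fold higher in the Ndrg-1 array.

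Neither Ndrg1 probe set was 2-fold higher in the clone transfected with it. Saturation of the brighter probe set was tested 3 times, and partial compression stays open. The first test, on genes with a high vector signal, came out as saturation predicts. Of 1046 genes with a vector signal at or above that of Ndrg1, 0 were 2-fold higher and 5 were 2-fold lower. Only 2 genes, Cd36 (971 to 2125) and Thy1 (1389 to 2141), met a further bound for which 3 were needed to speak against it. The first test decides nothing, because choosing genes by their vector signal favours those lower in the Ndrg-1 array. Of the 841 genes with a mean log2 signal at or above that of Ndrg1, 1 was 2-fold higher (Cd36) and 1 was 2-fold lower (Scin). The second test used the cre hybridisation spikes, whose signals ran from 1149 to 3469. Their median log2 ratio of -0.58 was no closer to 0 than the -0.54 of the dimmer spikes, which goes against saturation. The third took off each spike the median log2 ratio of the 300 gene probe sets nearest in signal, which was between -0.20 and -0.05 for the cre spikes. The cre median became -0.42 and that of the dimmer spikes -0.56. A cre median closer to 0 than -0.28 would have been read as saturation and one farther than -0.44 as speaking against it, and the value lies between, near the second bound. Exchanged labels stay open too: the brighter Ndrg1 probe set at 0.34 and the dimmer at -0.24 both lay within 2 SD of the disagreement between probe sets (0.46). The brighter lay just within the 2 SD of 0.36 found among bright genes. These comparisons are with 0, while the brightest decile of probe sets, in which the brighter lies, had a median of -0.13. Against probe sets of like signal its ratio could be larger and pass 0.36. Exchanged labels would stay open then too, because both probe sets had to lie beyond 2 SD to decide it. Probe sets that do not read the insert, and a clone with little extra transcript, were not tested, since neither the sequence of the insert nor protein was used here.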

How the results depend on the processing

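The spike scalings were added after seeing the data. The number of genes at least 2-fold apart depended mostly on the floor. With the floor at the 25th percentile 444 genes were higher and 463 lower of 12281 measured, and at the 75th percentile 23 and 34 of 5751. A higher floor leaves fewer genes to count and shrinks the ratios of genes at it in 1 array, while a lower floor admits dimmer signals. How many of the genes added by the lower floor reflect noise was not tested. Quantile normalization (150 higher, 143 lower) and the lowess correction (151 and 140) kept all 149 and 138 genes, the pseudocount gave 172 and 149 with 117 and 97 of the genes kept, and the median over probe sets gave 117 and 106. Scaled to the hybridisation spikes, 732 genes were higher and 43 lower, and scaled to the poly-A spikes 240 were lower; the share of higher genes was 51.9%, 94.5% and 29.6% under the main and these scalings. The Ndrg1 log2 ratio of 0.34 became 0.052 as the median over its probe sets, and 0.89 when scaled to the hybridisation spikes. Of the 12 lists outside the random range, between 8 and 12 stayed outside under each of the 8 settings fixed beforehand. The lists for cholesterol synthesis (medians from -0.56 to -0.41), fatty acids (-0.17 to -0.16), heat shock (0.20 to 0.31) and ATF4, CHOP and ER stress (0.09 to 0.21) stayed outside under all 8. S phase, NRF2 and ribosomal proteins stayed outside under 7, and oxidative phosphorylation and G2 and mitosis under 6. The mesenchymal and matrix list and the protease list did so under 5. Endothelial markers stayed outside under 6 of the 7 settings that gave them a median. The mesenchymal and matrix median was -0.04 under quantile normalization, -0.07 after the lowess correction and -0.03 with the floor at the 25th percentile (percentile 68.3). Ribosomal proteins turned to 0.0091 under quantile normalization, which gives both arrays the same signal distribution. Endothelial markers turned to -0.26 with the floor at the 25th percentile, which lets in members under the main floor, where 3 of 12 were measured. Other causes of these turns were not tested. The 76 genes named by the rule for a ratio of at least 2-fold had 608 values under the 8 settings, of which 473 moved by less than the SD between probe sets and 135 by more; such large ratios leave little room for a change of sign. Of 31 genes under 2-fold that were checked in the same way, most of them chosen after their values were seen, 1 changed sign, Hspa5, which ranged up to 0.26. Others, such as Lss (-0.93), Tcf7l2 (-0.73) and Hspa4l (-0.58), became 0 in 1 of the 8 settings, which was not counted as a change of sign. Dhcr7 (-0.97) ranged up to -0.10. The bounds of 3 genes at the floor in 1 array grew with the lower floor, Znrf3 from 0.98 to 1.83, Esam from 0.56 to 1.61 and Cldn1 from -0.41 to -1.42. Leaving out a replicate was not possible with 1 array per group. No paired analysis was possible because each group has 1 array.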

Other observations

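The test of sterol excess was chosen after the values were seen; the tests of neighbouring genes and of a signal trend in the cholesterol list were written before their results were seen.

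The genes of this paragraph were chosen after their values were seen; most were at least 2-fold apart and outside the fixed lists. The lipid droplet coat genes Plin1 and Plin4 had log2 ratios of 2.02 and 1.16. Plin2 and Plin3 were at -0.15 and -0.34, within 2 SD of the disagreement between probe sets (0.46). A second, dimmer probe set of Plin1, at the floor in the vector array, was at least 0.31 higher. G0s2, an inhibitor of triglyceride lipase, was at least 1.64 higher, and the lipase gene Pnpla2 was at -0.05. The pyruvate dehydrogenase kinase Pdk4 was at 1.40, with a dimmer probe set, at the floor in the vector array, at 0.35 or more. Thtpa, the thiamine triphosphatase, was at or under the floor in the vector array and at least 1.99 higher on the log2 scale. Hsd3b1, a steroid dehydrogenase, was at least 2.37 higher, and the progesterone receptor gene Pgr was at 1.28. On the lower side, Synpo2, an actin-bundling protein of muscle, was at -1.75, with other probe sets at -1.97 and, at the floor in the Ndrg-1 array, at -0.08 or lower, and Klhl41, a sarcomere protein, at -1.05. Gch1, the first enzyme of tetrahydrobiopterin synthesis, and its regulator Gchfr were at -1.36 and -1.59. The heat- and arsenite-inducible gene Zfand2a was at 1.84.

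Neighbouring genes tended to differ together. The 8545 genes were ordered along the chromosomes, and log2 ratios were limited to 1 in size. Genes 5 to 20 places apart correlated with r = 0.039 across genes, above the highest of 1000 shufflings (0.0092). After the lowess trend was removed r was 0.040. This could hardly have come out otherwise, because the trend was small. Median log2 ratios of the signal deciles ran from -0.13 to 0.04, and that size argues against the trend as the whole source. Of windows of 15 neighbouring genes, 18 had a median above that of every shuffled window (0.60), all on 1 chromosome. After the lowess correction 10 windows did so. Joined where they overlapped, the 18 windows made 2 runs. These went from Cspg4 to Uaca (28 genes, median 0.61, 23 higher) and from Chst2 to Nck1 (21 genes, median 0.58, 20 higher). The joined runs were not themselves compared with shufflings, and they do not mark sharp edges. Of the 113 genes between them, the 21 directly before Chst2, set apart after their values were seen, had a median of 0.47 with 18 above 0, and the other 92 had a median of -0.04. Without that chromosome r was 0.028, against a highest of 0.0072. A copy number difference between the clones is a candidate explanation for the runs, as a hypothesis; regional regulation was not tested, and 2 clones cannot show whether it came with the insert.

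The lower cholesterol synthesis list kept a median of -0.56 after the lowess trend on signal was removed. This could hardly have come out otherwise, because the trend was small and the random lists were already matched on signal. Median log2 ratios of the signal deciles ran from -0.13 to 0.04, and that size argues against the trend as the whole cause. Sterol excess in the Ndrg-1 culture, which would raise targets of the sterol sensor LXR, stays open: the median of 7 measured targets was 0.11, which is the value of Apoe and a lower bound, with Pltp at 1.06, Abca1 at -1.06 and Abcg1 at -1.94. The labels give both groups the same serum and selection. A difference in density or harvest between the 2 cultures could also lower the list and was not tested. An effect of Ndrg-1 is the biological explanation the design names, and it is confounded with clone and culture.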
